A study of Homo sapiens with 8 samples.

How the data were processed

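The series holds 8 ATAC-seq libraries from HEK293T cells, 4 labelled with an H2A lentivector and 4 with an H2A(E92K) lentivector. Groups and replicate numbers were taken from the sample titles. The labels describe the cells both as transfected and as carrying a lentivector, and give no treatment. They name genomic DNA as the material while the extraction note speaks of RNA, and they say that an outside company built the libraries.

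Each library has 1 headerless peak list with 10 columns in narrowPeak layout, and peaks were called per sample, not on pooled samples. Per the labels, reads were aligned to hg38. The aligner, the peak caller, the shift of reads for the Tn5 offset, and the handling of duplicates and mitochondrial reads are not given in the sources used here. Each of these steps changes widths, counts and significance of peaks, and it is not known whether they were alike for all libraries. The deposited score column is a whole number per peak that equalled 10 times the −log10 q, rounded down, in at least 99.99% of rows. The deposited fold column is a ratio, the enrichment of each summit over its local background. The deposited p-value and q-value columns are −log10 values as a peak caller writes them, and the smallest −log10 q in each list was 2, so the lists behave as if filtered at a q-value of 0.01. Peak numbers in the deposited names skip 4 or 5 values per list, so a few peaks were removed after calling. The lists hold chromosomes 1 to 22 and X and nothing else, so an analysis of every contig, chosen in advance, left all values as they were. The last peak end on each chromosome lay within the hg38 length of that chromosome.

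A peak was a distinct interval of a list. Rows that repeat an interval are further summits of that peak, and the summit with the smallest p-value stood for it. The fold and p-value of at least 99.86% of summits in every list are those of a Poisson test of a whole-number pileup n against a background b, with fold (n + 1)/(b + 1), within 0.001 of the −log10 p. The smallest b in a list is the genome-wide background and was used as the library's relative depth. Median recovered pileups at summits were 30 to 34 fragments. Total read numbers were not analysed here. Folds and significance were used only to describe, rank or filter peaks within a list. Deeper libraries detect weaker peaks, so a region missing from a list was not called there, which does not show that it was closed.

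The 8 lists were merged into consensus regions where peaks overlapped or touched, and a region was present in a library if at least 1 bp of it was covered by a peak. Regions present in 4 of 4 libraries of one group and 0 of 4 of the other were counted, and their total was compared over the 35 splits of 8 libraries into 4 and 4. Fisher's exact test was also run per region, but with 4 against 4 its smallest p is 0.0286. Values per library (number of peaks, covered length, median width, GC content, class, motif and chromosome shares, open promoters) were compared with an exact two-sided permutation test of the difference of means over 70 assignments. Benjamini-Hochberg adjustment was applied within each family: 4 classes, 24 motifs, 23 chromosomes and 27 gene lists. No permutation p over 70 assignments falls below 0.0286. A family can therefore pass only if several members reach that p together, and many in the larger families. Motifs, classes and chromosomes of group-specific regions were compared with the 4559 other regions present in exactly 4 libraries by two-sided Fisher's exact tests. Similarity was the base-pair Jaccard index, compared within and between groups over the same 35 splits. Correlations over the 8 libraries used exact permutations, and the correlation with group means removed used exchanges within groups.

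Annotation came from GENCODE version 44 on GRCh38, which is hg38. A promoter was the stretch within 1000 bp of a TSS of a basic protein-coding transcript. Peaks and regions were placed by their midpoint as promoter, exon, intron (inside a protein-coding gene and outside exons of such transcripts) or intergenic, in that order. A gene was open if a peak touched its promoter. Motifs were searched as consensus sequences on both strands of hg38 within 250 bp of a summit or of a region's centre, so a match shows a sequence and not binding. Motifs and gene lists were fixed before the data were examined, and so were the tests, the alternatives except those named as added later, and the rule for named items. By that rule the text names the 10 strongest group-specific regions per direction, ranked by the lowest of their 4 within-list percentiles, up to 10 genes per direction whose promoters separated the groups, any fixed-list gene with such a promoter, and the H2A genes. Of 40 interferon response genes fixed in advance, 39 were in the annotation. For the CTCF core, 100 backgrounds were also drawn at random after matching on the lowest within-list percentile in 10 bins. This replaced a single draw, chosen in advance, whose outcome depended on the random choice. Intervals on shares of regions are exact Clopper-Pearson intervals at 95% and cover counting error only.

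The alternatives chosen in advance were peaks with a q-value of 1e-05 or less, equal numbers of peaks (the 55527 most significant of each list), each replicate left out in turn, exchange only within replicate numbers, presence in at least 3 of 4 libraries, coverage of at least 50% of a region, windows of 500 bp, an overlap of at least 50% of both peaks, promoters of 2000 bp, list shares relative to all genes, a background matched on GC content in 10 bins, motif windows of 100 bp, and GC content over the whole peak. Alternatives added after seeing the data were thinning of the recovered pileups to the background of the shallowest library, which leaves the signal above background as it is and acts only on called peaks (peaks kept at a −log10 p of at least the strictest list's minimum), every summit row, and the lists without H2A replicate 4 and E92K replicate 2, the 2 libraries with most peaks.

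The counting over splits was tested on simulated data. With presence drawn for all 96872 regions and no group effect, the split of interest gave 137 regions and 30 of 35 splits gave as many. With 200 regions made specific to a group and each of their peaks missed with a chance of 5%, 82% of the 200 were recovered and 1 of 35 splits reached the total of 300. Each case was drawn a single time with independent libraries. The simulation therefore gives no rate of false results and does not cover features that libraries of a group share for other reasons, such as signal above background. All of 287 simulated pileups were recovered exactly. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.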

Results

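Accessible chromatin was profiled by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in 8 libraries of HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. According to the labels 4 libraries came from cells with a lentivector for histone H2A and 4 from cells with a lentivector for H2A(E92K). The E92K change replaces a glutamate of the acidic patch, the negatively charged nucleosome surface that many chromatin proteins contact, with a lysine. The comparison of the groups asks whether the mutant histone altered which regions are accessible. Each library had its own peak list, and the labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which can be purely technical. The H2A lists held 59759, 57439, 58937 and 62044 peaks in replicates 1 to 4. The H2A(E92K) lists, called E92K from here, held 58174, 61850, 57431 and 55527. Depth, read from the genome-wide background behind each list's p-values, was 2.71, 2.52, 2.53 and 2.93 fragments per position in the H2A libraries and 2.41, 2.68, 2.23 and 2.26 in the E92K libraries.

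A small set of accessible regions separated the groups. The 8 lists merged into 96872 regions, of which 36895 (38.1%) carried a peak in every library and 25683 (26.5%) in 1 library. Among the regions present in all 8 libraries 34.3% lay at promoters of protein-coding genes and the median width was 1030 bp, against 2.5% and 314 bp for the regions seen in 1 library. A peak in all 4 H2A libraries and no E92K library was found at 178 regions, called H2A-only, and the converse at 135 regions, called E92K-only. Their total of 313 exceeded that of each of the other 34 ways to split the 8 libraries into 4 and 4, which gave 105 to 185 regions with a median of 131.5 (exact over 35 splits, one-sided, p = 0.0286, the smallest share the design allows). No single region passed Fisher's exact test after Benjamini-Hochberg adjustment. The smallest exact p per region is 0.0286, which all 313 regions reached unadjusted. The median of 131.5 shows how many of the 313 could arise without any difference between the groups, and the 135 E92K-only regions taken alone equalled the highest count of another set of 4 libraries. The division between the directions changed to 132 H2A-only and 183 E92K-only regions when every library was thinned to the background of the shallowest one, a choice made after seeing the data. Thinning matched the background alone, and the signal above it still differed between the groups, as given below.

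**Figure D1:**
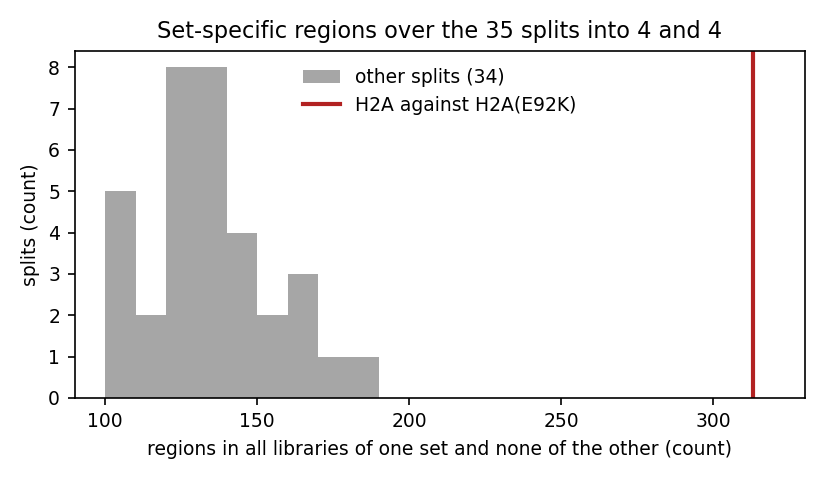
Histogram of the number of regions present in all 4 libraries of one set and in none of the other (x axis, count) over the 35 splits of the 8 libraries into 4 and 4 (y axis, number of splits). Grey bars are the 34 other splits, between 105 and 185 regions, and the vertical line is the split of H2A against H2A(E92K), at 313.

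The 10 strongest H2A-only regions, ranked by the lowest of their 4 within-list percentiles, lay outside promoters. Fold enrichment over background and −log10 q are the authors' values for each peak and serve here only to describe peaks within a list; coordinates are hg38, 1-based. The first was a 700 bp intergenic region on chromosome 11 (22875813 to 22876512), 15.7 kb upstream of the nearest coding TSS, that of CCDC179, and inside a long noncoding RNA gene. Its fold enrichment was 11.08 ± 1.09 (SD, n = 4), its −log10 q was 26.4 to 32.6, and it stood between the 67.1th and 75.2th percentiles of the H2A lists. An intergenic region on chromosome 5 (83608040 to 83608462) lay 74.3 kb into the direction of transcription from the TSS of HAPLN1, which encodes a link protein of the hyaluronan matrix, and had a fold of 9.46 ± 1.08 (SD, n = 4). Other regions sat in an intron of ERGIC1, a gene of ER-to-Golgi transport (chromosome 5, 172939158 to 172939655, fold 4.75 ± 0.41), and in an intron of NGDN, which encodes a nuclear protein that binds the translation factor eIF4E (chromosome 14, 23483059 to 23483696, fold 7.94 ± 1.12). A region on chromosome 1 (98048161 to 98048648) lay in MIR137HG, the host gene of a brain-expressed microRNA. It was 127.4 kb upstream of DPYD, the gene of the first enzyme of pyrimidine breakdown, and had a fold of 5.96 ± 0.94. On chromosome 2 (113604019 to 113604626) an intergenic region stood 22.9 kb upstream of the small GTPase gene RABL2A with a fold of 8.15 ± 0.92. On chromosome 20 (54103483 to 54103989) another stood 33.1 kb upstream of BCAS1, a gene of myelinating glia, with a fold of 7.6 ± 1.13. A region on chromosome 14 (106373479 to 106373809) overlapped the immunoglobulin heavy chain variable gene IGHV4-34 and had a fold of 8.57 ± 1.6. The list closed with a gene-poor stretch of chromosome 6 (9412907 to 9413377), 977.6 kb upstream of SLC35B3 (fold 7.34 ± 0.63), and an exonic region of RPS19BP1, a gene for a partner of ribosomal protein S19 (chromosome 22, 39529065 to 39529469, fold 2.72 ± 0.14).

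Of the 135 E92K-only regions 1 stood above the 50th percentile in all 4 lists and 21 had a q-value of 1e-05 or less in all 4, and of the 178 H2A-only regions 9 and 40. With only peaks of that q-value in every list, 143 regions were E92K-only and 138 H2A-only, and with equal numbers of peaks per list 154 and 148. The strongest lay in an intron of HEBP2, which encodes a heme-binding protein, 2 kb downstream of its TSS (chromosome 6, 138406006 to 138406458), with a fold of 2.9 ± 0.29 (SD, n = 4) and a −log10 q of 13.5 to 24.9. A region on chromosome 6 (149170785 to 149171443) stood 146.4 kb upstream of TAB2, an adaptor of the kinase TAK1 in inflammatory signalling, with a fold of 5.17 ± 0.59. An intron of PALM2AKAP2 held a 935 bp region (chromosome 9, 109812436 to 109813370, fold 5.63 ± 1.1), and an exon of TMEM68 a 264 bp region (chromosome 8, 55761174 to 55761437, fold 4.35 ± 0.14). Next came a region inside the annotated span of JUN, the AP-1 transcription factor gene, outside its exons and 3.9 kb downstream of its TSS (chromosome 1, 58779760 to 58780545, fold 1.95 ± 0.17). Upstream regions were found 25.1 kb from HMCN2, a gene of an extracellular matrix protein (chromosome 9, 130240450 to 130240885, fold 4.99 ± 1.21), and 6.3 kb from LATS2, a kinase of the Hippo pathway (chromosome 13, 21067566 to 21068211, fold 5.18 ± 0.85). The remaining regions lay in introns of LRRC63 (chromosome 13, 46220081 to 46220728, fold 5.33 ± 0.79) and NFIA, a nuclear factor I transcription factor gene (chromosome 1, 61091393 to 61091955, fold 3.98 ± 0.43), and on chromosome 4 (111650767 to 111651244, fold 4.85 ± 0.2), 494.4 kb upstream of FAM241A. The median distance to the nearest coding TSS was 65.9 kb for E92K-only and 29.9 kb for H2A-only regions. Promoter, exon, intron and intergenic shares of neither set differed from those of the 4559 other regions found in exactly 4 libraries (Fisher's exact test with Benjamini-Hochberg adjustment, 0 of 8 tests passed, 0 unadjusted).

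The core sequence bound by CTCF, the architectural protein of insulators and chromatin loops, was found within 250 bp of the centre of 20 of 178 H2A-only regions (11.2%, exact 95% interval 7 to 16.8) and 3 of 135 E92K-only regions (2.22%, exact 95% interval 0.46 to 6.36). Other regions present in exactly 4 libraries carried it in 229 of 4559 cases (5.02%). Against that background the H2A-only share had a Fisher's exact p of 0.0016, which did not pass Benjamini-Hochberg adjustment over 48 tests of 24 motifs in both directions (adjusted p = 0.0746). None of the 48 passed, and 2 had an unadjusted p under 0.05. The other was the T-box site, absent from the E92K-only regions and present in 3% of the background (Fisher's exact p = 0.0337, adjusted p = 0.717). Of the 10 H2A-only regions named above 5 held the CTCF core. These included the region near CCDC179 (CCAGCAGGTGGC at 22876029 to 22876040), the ERGIC1 intron (CCAGCAGGGGGC at 172939217 to 172939228 on the minus strand) and the region near RABL2A, which had 2 sites. The others were the IGHV4-34 region (CCAGCAGGTGGC at 106373565 to 106373576 on the minus strand) and the RPS19BP1 exon (CCAGCAGATGGC at 39529395 to 39529406 on the minus strand). None of the 10 named E92K-only regions did. The adjusted p for the H2A-only regions ranged from 4e-05 without H2A replicate 4 to 0.84 at q-values of 1e-05 or less. At that threshold the E92K-only regions passed instead, with the core in 1 of 143 (Fisher's exact test, adjusted p = 0.0276).

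Across all peaks of a library the CTCF core was found within 250 bp of the summit in 7.66% ± 0.12 of H2A peaks and 7.36% ± 0.0889 of E92K peaks (SD, n = 4 each, difference −0.296 points, lower in all 4 E92K libraries than in any H2A library). The GATA site went the other way, with 6.49% ± 0.0901 in H2A and 6.8% ± 0.0816 in E92K peaks, as did the nuclear factor I palindrome, with 0.151% ± 0.0096 and 0.19% ± 0.009. The HNF1 site (0.0311% ± 0.0041 against 0.0262% ± 0.0006) was lower in E92K, but in few peaks per list and narrowly (at most 0.027% in E92K, at least 0.0274% in H2A). The partial REST site (2.89% ± 0.0175 against 2.8% ± 0.0337) and the T-box site (2.2% ± 0.0359 against 2.1% ± 0.0552) were also lower in E92K. For the T-box site the separation was narrow too (at most 2.163% in E92K, at least 2.172% in H2A). These 6 of 24 motifs separated the groups completely, each with an exact two-sided permutation p of 0.0286, the smallest that 70 assignments allow. After Benjamini-Hochberg adjustment each of these permutation p-values was 0.114, so none of the 24 passed. With a smallest p of 0.0286, adjustment over 24 motifs can pass only if many separate the groups together. The adjusted values therefore do not argue against a difference at a few motifs.

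**Figure D2:**
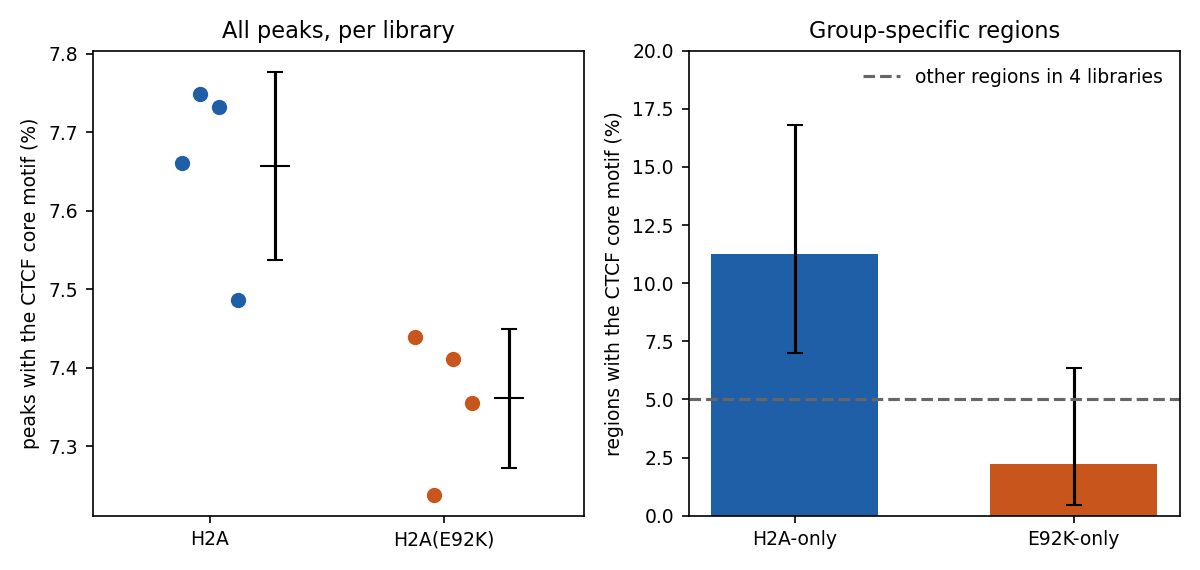
Left, share of each library's peaks with the CTCF core within 250 bp of the summit (y axis, %, not starting at 0), 1 point per library, with the mean and SD of 4 libraries beside the points. Right, share of group-specific regions with the core within 250 bp of the centre (y axis, %), with exact 95% intervals, 11.2% for 178 H2A-only and 2.22% for 135 E92K-only regions, and the dashed line at the 5.02% of other regions in 4 libraries.

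The number of promoters with a peak was alike in the groups. A peak within 1000 bp of a TSS was present for 13929 ± 63 (SD, n = 4) of 19609 protein-coding genes in H2A and for 13886.5 ± 84.5 in E92K libraries, a difference smaller than the spread (exact two-sided permutation p = 0.457). All 8 libraries had such a peak at 13341 genes (68%) and none at 5025. Promoters with a peak in 4 libraries of one group and none of the other numbered 6, a total that 3 of the 35 splits reached and that was at most 8 in another split (exact p = 0.0857). Of these, 5 were open in H2A only. They belonged to MYOG, the muscle regulator myogenin (chromosome 1, peaks from 203084243 to 203085118, fold 3.87 ± 0.16), and to SLC5A5, the sodium-iodide symporter (chromosome 19, 17871707 to 17872669, fold 2.6 ± 0.31). The MYOG peaks lay inside the gene, whose TSS is at 203086012 on the minus strand, and reached its promoter only at the edge. Their merged region was not among the H2A-only regions, so an E92K peak touched it outside the promoter. For MYOG the separation thus depended on where the promoter was cut off. The next were TMEM225B (chromosome 7, 99598081 to 99599071, fold 3.79 ± 0.36), ASCL5, a basic helix-loop-helix factor (chromosome 1, 201127269 to 201128034, fold 2.62 ± 0.24), and PHF2, a histone demethylase (chromosome 9, 93575721 to 93578440, fold 2.47 ± 0.25). The 1 open in E92K only was that of CLRN1, mutated in Usher syndrome (chromosome 3, 150972559 to 150973029, fold 3.64 ± 0.76, SD over 4 libraries). By Fisher's exact test these 6 genes had an unadjusted p under 0.05 and 0 of 19609 passed Benjamini-Hochberg adjustment. With q-values of 1e-05 or less 9 promoters separated the groups against at most 8 in another split (exact p = 0.0286), but of the 6 named here only those of MYOG and SLC5A5 did, and these 2 no longer did with promoters of 2000 bp.

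No test of the number of open promoters passed for the 27 gene lists fixed in advance (exact two-sided permutation tests with Benjamini-Hochberg adjustment, 0 passed, 0 with an unadjusted p under 0.05). Adjustment over 27 lists could pass only if many lists separated the groups together. The H2A, acidic patch, BAF, glycolysis, DNA repair, cell cycle and heat shock lists had the same count in all 8 libraries, so their tests could show nothing. The counts record whether a peak was called and not its strength. No list member had a promoter open in 4 libraries of one group and none of the other, so 0 members passed Fisher's exact test either adjusted over the list alone or over all genes. Genes for chromatin and growth were open nearly throughout. All 28 BAF remodeler genes, all 40 DNA repair genes and all 37 cell cycle genes had a promoter peak in every library, as did 30 of 31 genes of the ISWI, CHD and INO80 remodelers, 29 of 31 polycomb genes and 78 of 80 ribosomal protein genes. Of 26 genes for proteins that bind the acidic patch or depend on it, 25 were open in all 8 libraries, among them RCC1, SIRT6, DOT1L and SMARCB1, and the cytosolic DNA sensor gene CGAS was open in none. Likewise open in all 8 were 23 of 24 glycolysis genes, 24 of 25 p53 targets, 27 of 28 immediate early genes and 15 of 17 heat shock genes. Interferon response genes were open in 30.2 ± 1.26 (SD, n = 4) of 39 cases in H2A and in 29 ± 0.816 in E92K libraries, 28 of them in all 8.

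Lineage genes gave a mixed picture, and no test of their lists passed. Among kidney genes 16 of 32 were open in all 8 libraries, including the nephron progenitor genes SIX2, WT1, PAX2 and SALL1, and 14 in none, including the tubule genes UMOD, AQP1 and SLC34A1. Neuronal promoters were mostly open, 27 of 35 in all 8 libraries, among them NEFL, INA, SYN1 and TUBB3. So were 17 of 28 fibroblast and mesenchymal genes, 26 of 39 HOX genes and 84 of 128 developmental transcription factor genes. Of all 19609 protein-coding genes 68% were open in all 8 libraries, a share that the fibroblast, HOX and developmental lists did not exceed. Fewer hematopoietic (5 of 23), hepatocyte (4 of 18) and endothelial (4 of 14) markers were open in every library. No library had a promoter peak at 371 of 381 olfactory receptor genes, 80 of 93 cancer testis antigen genes and 27 of 53 clustered protocadherin genes, while 410 of 508 ZNF zinc finger genes were open in all 8. The smallest p of the 27 lists belonged to keratin and epithelial genes, open in 10 ± 0.816 (SD, n = 4) of 23 cases in H2A and 11.8 ± 0.5 in E92K libraries (exact two-sided permutation p = 0.0571, adjusted p = 1). Most of it came from CLDN4, a tight junction claudin open in 1 H2A and 4 E92K libraries, and CDH1, the gene of E-cadherin, open in 2 and 4, both picked out after their values were seen.

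Replication-dependent histone genes, whose promoters cluster on chromosomes 6 and 1, were open in all 8 libraries in 46 of 69 cases and in none in 22. The exception was H3C4, open in 3 E92K libraries and no H2A library and named after its value was seen (46 ± 0 against 46.8 ± 0.5 open genes, SD, n = 4, exact two-sided permutation p = 0.143, adjusted p = 1). A peak lay over 21 of the 26 H2A family genes, or within 1 kb of them, in all 8 libraries, and over 5 in none. No H2A gene thus distinguished the groups by the presence of a peak. Within-list percentiles were lower in all 4 E92K libraries than in any H2A library for H2AX (93.9 to 96.5 against 96.6 to 99), H2AZ1 (86.2 to 91.9 against 92.6 to 94.8), H2AC4 and H2AC17. For none of the family were they higher in this way. These genes were picked out after their values were seen, and no test was run on them. Over the 8 libraries of both groups together, the variants H2AZ2, H2AX and H2AZ1 had median within-list percentiles of 98.9, 96.6 and 92.3. The replication-dependent H2AC11, H2AC20 and H2AC4 stood at 95.1, 93.5 and 92.4, and the macroH2A genes MACROH2A2 and MACROH2A1 at 80.3 and 76.2. The kinds of gene were not ordered in this way throughout. The replication-dependent H2AC25 stood at 98.5 and H2AC8 at 71.2, and the variant H2AJ at 60.7. Lowest were H2AC19 and H2AC18 on chromosome 1, near-identical copies that stood at 57.7 and 49.2 and whose reads cannot be assigned with certainty. The genes without a peak were H2AB1, H2AB2 and H2AB3 on the X chromosome, to which the same limit on assigning reads applies, and H2AC1 and H2AC14 on chromosome 6.

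For the size of the lists and for their classes no test passed after adjustment. H2A lists held 59545 ± 1923 (SD, n = 4) peaks over 41.3 ± 1.67 megabases and E92K lists 58246 ± 2649 peaks over 40.4 ± 2.59 megabases, differences within the spread (exact two-sided permutation p = 0.429 for peaks and 0.571 for covered length). The median peak was 578 ± 6.98 bp wide in H2A and 583.5 ± 13.5 bp in E92K libraries (SD, n = 4, exact permutation p = 0.6). Peaks at promoters made up 23.2% ± 0.668 in H2A and 23.7% ± 0.982 in E92K lists, intergenic peaks 38.7% ± 0.262 and 39.1% ± 0.502 (SD, n = 4, exact permutation p = 0.514 and 0.2). Intronic peaks made up 35.5% ± 0.4 and 34.7% ± 0.566 and exonic peaks 2.64% ± 0.0616 and 2.56% ± 0.0506, the closest to the threshold among these classes (exact permutation p = 0.0857 and 0.0571, both 0.171 after Benjamini-Hochberg adjustment over 4 classes). Median GC content around summits was 49.8% ± 0.191 and 49.7% ± 0.412 (exact permutation p = 0.83). Depth was 2.67 ± 0.191 fragments per position in H2A and 2.39 ± 0.204 in E92K libraries (SD, n = 4, exact two-sided permutation p = 0.114), and the number of peaks rose with it over the 8 libraries (Pearson r = 0.886, exact permutation p = 0.0036, Spearman rho = 0.929, exact permutation p = 0.0022). Without H2A replicate 4 and E92K replicate 3, the libraries farthest from the median depth, r was 0.877. With the group means removed, a test added after the data were seen, r was 0.938 (exact p = 0.0052 over 576 exchanges within groups). Thinned to a common background, the lists held 56198 ± 835 peaks in H2A and 56908.5 ± 1241 in E92K libraries (SD, n = 4, exact permutation p = 0.371). The median pileup at the 36895 regions called in every library was 19.3 ± 0.507 times the background in H2A and 20.5 ± 0.396 times in E92K libraries, higher in all 4 E92K libraries than in any H2A library (SD, n = 4, exact two-sided permutation p = 0.0286, a test added after the data were seen). The complete separation was narrow, with 19.8 in H2A replicate 4 and 19.9 in E92K replicate 1. The medians are whole numbers (58 and 48 fragments there), and a change by a single fragment could have undone it.

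**Figure D3:**
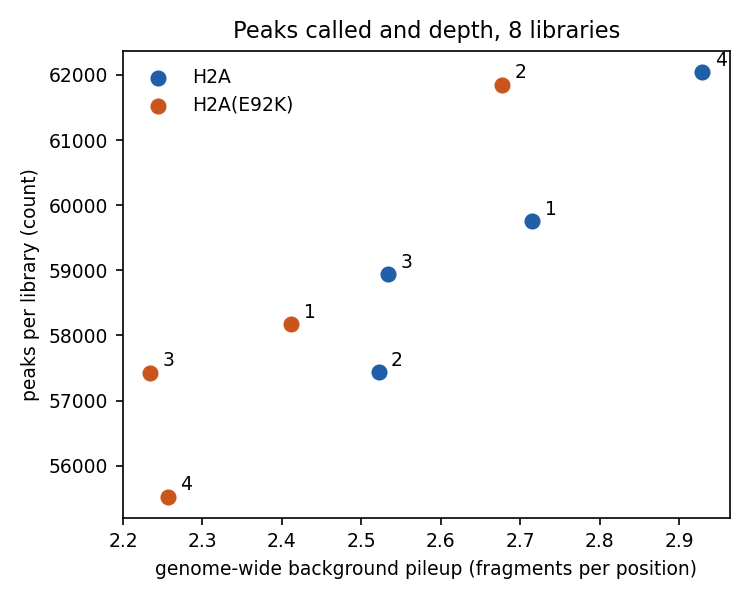
Number of peaks in each list (y axis, count, not starting at 0) against the genome-wide background pileup of the library (x axis, fragments per position), 1 point per library with its replicate number. Lists range from 55527 to 62044 peaks and deeper libraries have longer lists (r = 0.886 over 8 libraries).

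Libraries of one group resembled each other slightly more than libraries of the other. The mean base-pair Jaccard index, the shared divided by the total covered length of a pair of lists, was 0.638 ± 0.0034 (SD) over 12 pairs within groups and 0.629 ± 0.0055 over 16 pairs between them. The difference of 0.0088 was larger than in each of the other 34 splits, whose highest value was 0.0038 (exact over 35 splits, one-sided, p = 0.0286). Without H2A replicate 1 the difference was 0.0081 and another split reached it (exact p = 0.0571). Over chromosomes, the X carried 3.59% ± 0.0126 of H2A peaks and 3.44% ± 0.0333 of E92K peaks, chromosome 8 4.04% ± 0.0307 and 3.96% ± 0.0093, and chromosome 11 4.72% ± 0.0118 and 4.69% ± 0.0158 (SD, n = 4). Each was lower in all 4 E92K libraries than in any H2A library, chromosome 11 only narrowly (at most 4.705% in E92K, at least 4.709% in H2A). The exact two-sided permutation p was 0.0286 for each, but none of the 23 chromosomes passed Benjamini-Hochberg adjustment (adjusted p = 0.219 for these 3). Nor did any of 46 tests of where group-specific regions lay by chromosome, of which 4 had an unadjusted Fisher's exact p under 0.05. For the shares per library, adjustment over 23 chromosomes can pass only if many separate the groups together, so a difference at a few could not have passed.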

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

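Within each group of 4 libraries, the highest or lowest value was tested for standing apart from the others (Dixon's test at its 95% critical value), a test planned for every measure per library. It picked out 5 of 118 groups tested, and chance alone picks about 1 in 20. No biological explanation was tested for them, since no label separates libraries within a group. H2A replicate 4 had the ZNF143 site in 0.166% of its peaks, against 0.173 to 0.174% in the other H2A libraries. H2A replicate 3 had 2.569% of its peaks on chromosome 15, against 2.632 to 2.636%. In E92K replicate 2, the NF-κB site was present in 8.323% of peaks, against 8.564 to 8.608% in the other E92K libraries. The same library had 5.054% of its peaks on chromosome 12, against 4.919 to 4.942%, and 2.081% on chromosome 18, against 1.997 to 2.009%. E92K replicate 2 also had the longest list of its group, with 61850 peaks.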

How the results depend on the processing

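Thinning to a common background, the lists without the 2 libraries with most peaks, and every summit row were chosen after the data were seen; the other alternatives were chosen in advance. Of the results that answer a comparison, 226 values under the alternatives kept their direction and side of the threshold, 48 counts changed in size, 6 passed a threshold they had missed, 5 no longer passed and 9 changed sign. Values are E92K minus H2A unless they are counts. Where no reason is given, the cause was not tested.

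The total of regions specific to a group exceeded that of every other split under each alternative run. It was 1517 (816 H2A-only, 701 E92K-only; at most 1169 in another split) with presence in at least 3 of 4 libraries, and 555 to 633 (270 to 369 H2A-only, 217 to 321 E92K-only; at most 419 to 508 in another split) when a replicate was left out; these rules admit more regions by construction. The closest was 567 against 508 without H2A replicate 4, and E92K-only regions alone were fewer than in another set of libraries in some cases (217 against 301 without H2A replicate 2). With exchange only within replicate numbers the total of 313 and the similarity difference of 0.0088 no longer passed, because 8 splits allow no exact p below 0.125; the replicate numbers did not pair the samples. Without the 2 libraries with most peaks, 10 splits allow no exact p below 0.1: the total was 958 (546 H2A-only, 412 E92K-only; at most 661 in another split), the similarity difference 0.0093, 27 promoters separated the groups, and median GC content differed by 0. Leaving out a replicate gave similarity differences of 0.0079 to 0.0108, and 0.0081 without H2A replicate 1 (exact p = 0.0571).

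With q-values of 1e-05 or less the exonic share differed by −0.0651 points (exact permutation p = 0.0286, unadjusted) and 9 promoters separated the groups. This number was 33 with presence in at least 3 of 4 libraries, and 9 to 20 when a replicate was left out, passing only without H2A replicate 3 (20, exact p = 0.0286). With equal numbers of peaks median width differed by −6.5 bp and the promoter share by −0.0252 points, both with the sign changed, and the intronic (−0.4174 points) and intergenic (0.52 points) shares reached an unadjusted exact permutation p of 0.0286. After thinning the differences were 710.25 peaks, −10.75 bp in width and −0.2487 points in promoter share, all with the sign changed and none past the threshold.

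When a replicate was left out, covered length differed by −2009145.1667 to 76032.8333 bp (positive without E92K replicate 4), median width by −0.6667 to 9 bp and GC content by −0.2495 to 0.0832 points (signs changed without E92K replicate 2), and the intronic share by −1.062 to −0.6297 points. The intronic difference of −1.062 points, without E92K replicate 2, reached an unadjusted exact permutation p of 0.0286. The number of motifs past the adjusted threshold in group-specific regions was 1 with q-values of 1e-05 or less, coverage of at least 50% of a region, windows of 500 bp or without the 2 libraries with most peaks, and 0 to 4 when a replicate was left out. For classes it was 2 without the 2 libraries with most peaks and 0 to 2 when a replicate was left out, and for chromosomes 0 to 1. Of the 20 named regions 3 were weaker with coverage of at least 50% and none under another alternative run. Leaving out libraries could not have weakened them, since a region specific to a group stays so among the remaining libraries. Nor could the q-value filter, since the lowest −log10 q of any of their peaks was 5.9. Equal numbers of peaks dropped only the weakest peaks, and these regions were chosen as the strongest. Of the 6 named promoters 4 were weaker with q-values of 1e-05 or less (TMEM225B, ASCL5, PHF2, CLRN1), 3 within 2000 bp (MYOG, SLC5A5, PHF2), 2 with equal numbers of peaks (PHF2, CLRN1) and 1 after thinning (PHF2), so each was weaker under at least 1. Depth limits what a missing peak means, since the shallowest library had a background of 2.23 and the deepest of 2.93 fragments per position.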

Other observations

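The test of depth by thinning, the count of regions strong in one group and absent in the other, and the test of peak strength in its final form were chosen only after the results were seen. The counts over splits and at q-values of 1e-05 or less were chosen in advance, but what they would have to show was set down after they were seen. The tests of deletions, GC content, a group difference at CTCF sites and X copy number were chosen before their results. The labels do not say how the cells of each group were derived, so whether a difference comes from the mutant histone or from the derivation of the cells stays open throughout.

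Clustered protocadherin genes, whose promoters use CTCF sites, had 15.2 ± 0.957 (SD, n = 4) of 53 promoters open in H2A and 13.5 ± 1.91 in E92K libraries (exact two-sided permutation p = 0.257, adjusted p = 1). PCDHA1 was open in 3 H2A libraries and no E92K library, and PCDHA2, PCDHA8, PCDHA10, PCDHGB3 and PCDHGB7 in 4 and 3. Others went the opposite way, such as PCDHGB1, open in 0 and 2. NPHS1, the gene of the podocyte protein nephrin, was open in 4 H2A libraries and 1 E92K library, as were ZNF467 and ZNF469. NEUROD6, a neuronal transcription factor gene, was open in 1 and 4. All these genes were picked out after their values were seen.

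The 313 regions specific to a group, such as those near CCDC179 and HEBP2, were weighed first. Chance is argued against for their total, since 1 of 35 splits, the split of interest, gave as many and the highest other gave 185. It is not excluded, because 35 splits allow no share below 0.0286. For the similarity of libraries 1 of 35 splits was as large as well (0.0088 against at most 0.0038). Without H2A replicate 1 the difference was 0.0081 and another split was as large, so chance was not argued against there. Chance cannot be excluded for the 6 promoters such as those of MYOG and CLRN1 (3 of 35 splits, at most 8 in another). A difference in depth would bring H2A-only regions down to the level of other sets of 4 libraries after thinning. There were 132, against at most 108, although signal above background was lower in H2A libraries (19.3 against 20.5 times), so depth is not the whole cause. Peaks near the calling threshold stay open for most of the regions. With q-values of 1e-05 or less 281 regions separated the groups, against at most 127 in another split, but a stricter threshold has peaks near it as well and this decides nothing. A narrower count took regions with a q-value of 1e-05 or less in all 4 libraries of one group and no peak in the other. There were 61, against at most 24 in another split and a median of 14.5. Such peaks are thereby argued against as the whole cause of this count. It does not show which of the 61 differ, since other splits gave such regions as well. Deletions of every copy that span more than 1 peak would place specific regions side by side, which held for 0.6% of them (2 of 313, exact 95% interval 0.1 to 2.3). Gains, or losses of only some copies, can leave neighbouring strong peaks called in all libraries, so this test cannot decide about them. The 2 are the IGHV4-34 region and its neighbour (chromosome 14, 106417559 to 106417903), both H2A-only and both with the CTCF core, so for this pair a deletion in the E92K cells stays open. Changes of DNA confined to 1 peak were not tested. The excess of H2A-only over E92K-only regions is another matter. After thinning there were 183 E92K-only and 132 H2A-only regions, where 135 and 178 had been found. Depth and the higher signal of the E92K libraries, which thinning left, cannot be told apart as reasons, and neither direction can be called the more common. That higher signal may come from library quality or from the cells, and its part in the 183 was not tested. A difference between the cells of the groups at a small set of regions, through E92K or through their derivation, may explain the total, and the data cannot separate these.

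The CTCF core in H2A-only regions, such as the ERGIC1 intron and IGHV4-34, was weighed second. Matching on GC content left the excess nearly as it was, with a share of 11.2% against 5.06% (Fisher's exact p = 0.00162, unadjusted), which argues against GC content as its whole cause. As in the main test, the excess did not pass adjustment over the motif tests (Fisher's exact test, adjusted p = 0.078), so the match does not settle whether it is more than chance. The strength of the peaks stays open. Against backgrounds matched on within-list percentile, with a median share of 6.4%, Fisher's exact p was under 0.05 in 96 of 100 draws and up to 0.0743 in the others. More than 95, by over the standard error of 1.96, was asked for. The single draw chosen in advance first gave an exact p just under 0.05, with percentiles rounded, and was replaced by the 100 for that reason; with unrounded percentiles it gave 0.0186. The limit was first set, after that value was seen, so that 95 sufficed, and was then tightened because a count at the limit decides nothing. Peak strength may therefore account for part of the excess. H2A-only and E92K-only regions differed in their share (11.2% against 2.22%, Fisher's exact p = 0.00199), but 1 of 49 other sets of 4 libraries had a share as high as the H2A-only regions (11.8%) and 13 of 49 one as low as the E92K-only regions. A loss of accessibility at CTCF sites in E92K and variation between libraries thus cannot be told apart. The lower share of CTCF peaks in E92K libraries (−0.513 points with q-values of 1e-05 or less, −0.506 after thinning) had the same sign under each alternative run.

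The lower share of X chromosome peaks in E92K, 4.03% below that of H2A, was weighed last. A lower copy number of the X would lower the pileup at X regions open in all libraries. Over 1310 such regions the ratio of X to autosomal pileup was 1.06 ± 0.036 (SD, n = 4) in H2A and 1.04 ± 0.012 in E92K libraries, a quotient of 0.974 with a standard error of 0.0175 (exact two-sided permutation p = 0.2). A loss to below 0.95 in all cells is thereby argued against by little more than that error, and a smaller one, in part of the cells, could still contribute. No biological explanation was tested for the X.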
